A study of Homo sapiens with 18 samples.

How the data were processed

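The deposited files hold counts of reads per gene made by the authors with STAR 2.7.10b on GRCh38, per the processing notes, with 3 count columns and 4 summary lines that were left out of the gene counts. Per the labels, inserts of 24 mm carried 400000 A549 or 500000 BEAS-2B cells plated 24 h ahead and exposed for 4 h at 100 mL/min and 85% relative humidity, RNA was extracted with TRIzol, and libraries were made with a TruSeq mRNA kit. The design assumed unstranded libraries, but in all 18 libraries the column for one strand held 11.7 to 17.1 times the counts of the other. The stranded column was therefore used, under the rule set in the design, and the column that ignores strand became an added alternative. Groups came from the labels, 6 groups of 3. Nothing in the labels says whether the 3 samples of a group came from separate cultures or exposures, so p-values measure the spread between these samples, which may be technical. No 2 libraries held the same counts. Of 62649 gene IDs 62625 had a gene name, and 58225 were in GENCODE v29, from which positions and lengths were taken.

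All fits used R 4.3.3. Genes passed filterByExpr, libraries were scaled by TMM (factors from 0.72 to 1.52 in BEAS-2B cells), and edgeR 4.0.16 quasi-likelihood tests with robust dispersion were run on the 9 libraries of a line, with a Benjamini-Hochberg adjusted p under 0.05 taken as passing. Differences between lines were the interaction term of a fit of all 18 libraries, as BEAS-2B minus A549. Adjusted p values of genes are from edgeR unless another tool is named. Standard errors of log2 fold changes were derived from the edgeR test statistic, and CPM values are group mean ± SD. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the 23 lists of a comparison. The biological coefficient of variation was 0.209 in A549 cells, 0.299 in BEAS-2B cells and 0.258 in the joint fit. Log values used a prior count of 2, and random draws the seed 2024.

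The 23 lists were NRF2 targets, HSF1 heat shock response, ATF4 integrated stress response, endoplasmic reticulum chaperones, AhR targets, p53 targets, NF-kB targets and cytokines, immediate early genes, mitosis genes, DNA replication genes, Fanconi anaemia and homologous recombination, metallothioneins and zinc export, cholesterol synthesis, TGF-beta targets and extracellular matrix, proteasome subunits, HIF-1 hypoxia targets, interferon-stimulated genes, aldehyde and carbonyl metabolism, tubulin and actin cytoskeleton, ribosomal proteins, mitochondrially encoded mRNAs, replication-dependent histone mRNAs, and markers of other lung cell types. Genes named in the text are 27 fixed sentinel genes, the 6 highest and 6 lowest fold changes of each comparison among protein-coding genes that passed with a mean of at least 5 CPM, at least 1 count in every library and no overlap of the groups (the last condition was dropped for line differences), and up to 4 passing members of each list. Some genes that this rule gave are not reported here. HSPA1A, a sentinel whose copy HSPA1B is near-identical, lay under the count minimum and was not tested.

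Alternatives for each comparison were DESeq2 size factors, upper-quartile scaling, no or a stricter low-count filter, the DESeq2 1.42.0 Wald test, limma-voom, the sample number as a block, offsets for GC content and length, both together, a minimum of 2-fold and each library left out in turn. Comparisons within a line were also run on only the libraries compared and with all 18 libraries in one fit. Lists were tested with DESeq2 size factors, upper-quartile scaling, the block, each library left out, an estimated correlation and fry. Camera compares a list with all other genes, while fry tests whether a list moves on balance one way, so the 2 ask different questions, and ranges over settings include both. They were not tested with other low-count filters, the DESeq2 Wald test, limma-voom, only the libraries compared, all 18 libraries or counts that ignore strand. The offsets were smooth splines of GC content and exonic length fitted per library with mgcv 1.9.3, where the plan named loess, and covered 96.9% of tested genes. Exonic length is the union of all annotated exons of a gene. The offsets did not include gene span, so a call kept with them is not shown to be free of a trend with span. Alternatives added after the files were seen were the offsets for lists, without and with the block, counts that ignore strand for genes, library size alone, sample numbers 1 and 2 only, and BEAS-2B without control 1 and complete 3, the former because it stood apart from the other controls (response score 0.343 against -0.138 and -0.205) and the latter for its reads outside genes. The last 3 were run for lists too. All settings run for lists are called the list settings.

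The labels give each sample a number, 1 to 3, shared across the groups of a line. The numbers were taken as pairs where the deviations of every same-numbered pair from their group means correlated over 0.1, a hint from the data and not the labels. This held for all 3 comparisons in A549 cells (lowest r of 0.274 for complete smoke and control, 0.719 for complete and filtered, 0.318 for filtered and control) and in BEAS-2B cells for complete and filtered (0.492) and for filtered and control (0.317, where number 2 correlated better with another number, at 0.659). It did not hold for complete smoke and control in BEAS-2B cells. The response score averages, over genes that passed for the mean of both exposures against control, the log2 change of a library from the control mean, signed by the direction of change, so the control mean is 0 by construction. Similarity of responses was compared with 20 simulations of unchanged groups.

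In simulated counts with known changes, edgeR found 5.97% of 1.5-fold, 55.2% of 2-fold and 97.0% of 4-fold changes at A549 spread (6 false of 111 calls over 15012 genes), and 0%, 5.97% and 71.2% at BEAS-2B spread (2 false of 53 calls over 15805 genes). Absence of a call in BEAS-2B cells therefore says little about changes of 2-fold or less. Some values used in the closing section had been seen when its tests were written, as stated there. A test of scaling between libraries for the trend with gene span was withdrawn because scaling moves all genes alike. MT-ND6 and markers of other cell types were kept in the tests, and no genome sequence was used here.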

Results

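Gene expression was measured by mRNA sequencing in a pair of human lung epithelial lines exposed for 4 h at the air-liquid interface, where cells on a porous insert meet the aerosol directly. A549 is an alveolar line from a lung carcinoma, and BEAS-2B is an immortalised bronchial line. Each line received complete wood smoke, filtered wood smoke or clean air, with 3 libraries in each of the 6 groups and 18 in all. The series title places the question in the gas phase of the smoke and its carbonyl compounds, which filtered smoke still carries. Counts assigned to genes ranged from 14.4 M to 21.4 M per library in A549 cells, with group means of 17.1 ± 2.67 (clean air), 17.8 ± 3.51 (complete) and 16.8 ± 2.03 M (filtered; mean ± SD, n = 3). In BEAS-2B cells they ranged from 28.5 M to 55.0 M, with group means of 30.2 ± 1.45, 41.6 ± 12.4 and 46.0 ± 7.72 M in the same order. Reads that mapped to several places took a larger share after exposure. In A549 cells that share was 9.94% ± 0.288 with clean air, 11.3% ± 0.852 with complete and 11.4% ± 0.951 with filtered smoke, and in BEAS-2B cells it was 8.50% ± 0.723, 18.3% ± 11.7 and 13.9% ± 4.59 (SD, n = 3). The BEAS-2B libraries with complete smoke held 12.9%, 10.2% and 31.7%, so library 3 carries much of that mean. Each of the 4 exposed groups lay fully above its controls (2-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The share of uniquely mapped reads outside genes was lower by 2.7 and 3.67 percentage points in A549 cells with complete and filtered smoke and by 3.35 points in BEAS-2B cells with filtered smoke (exact permutation p = 0.1 each). With complete smoke it was 5.07% ± 6.51 in BEAS-2B cells, against 5.10% ± 1.47 with clean air (exact permutation p = 1), and library 3 of that group stood at 12.6%.

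The first comparison asked what complete wood smoke did to A549 cells. Immediate early transcription factors and the heat shock gene HSPA6 were among the largest rises. EGR3, an immediate early transcription factor (ENSG00000179388, GRCh38 chromosome 8, 22687659 to 22693302), rose from 0.234 ± 0.139 to 16.8 ± 5.89 CPM (counts scaled to library size; mean ± SD, n = 3), a log2 fold change of 6.20 ± 0.56 (SE; adjusted p = 0.000822). HSPA6, a stress-inducible HSP70 chaperone (ENSG00000173110, chromosome 1, 161524540 to 161526910), rose from 4.5 ± 2.33 to 243 ± 52.4 CPM (5.77 ± 0.52, adjusted p = 0.000822). HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), fell from 1381 ± 156 to 378 ± 134 CPM (-1.87 ± 0.24, adjusted p = 0.00152). MDM2, the ubiquitin ligase that restrains p53, fell from 439 ± 19.9 to 118 ± 41.4 CPM (-1.89 ± 0.35, adjusted p = 0.00584). In all, 4951 of 15244 genes passed the threshold, 2371 of them higher and 2580 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1887 of these also changed at least 2-fold.

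Of the 32 immediate early genes tested, 24 rose, 1 fell and 7 did not pass, and adjusted over the list alone 25 rose and 2 fell (list median 1.46 on the log2 scale, camera adjusted p = 1.61e-10). EGR2 (5.72), FOSB (4.36) and FOS (3.34) were among those that rose. Among 23 heat shock genes controlled by HSF1, 10 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.0471), with FKBP4 at 1.07. That call was lost without control 2 (adjusted p = 0.0891), control 3 (0.0797) or complete 3 (0.184). The proteasome list had 12 of 33 subunits higher and none lower (17 adjusted over the list alone; median 0.60, adjusted p = 6.94e-05). Among 36 DNA replication genes 9 rose and 1 fell (6 and 0 adjusted over the list alone; adjusted p = 0.0042), E2F1 among them (1.23), a transcription factor that drives entry into S phase. Enzymes of aldehyde and carbonyl metabolism rose in 6 of 30 cases with none lower (12 adjusted over the list alone; median 0.44, adjusted p = 0.000749). Among these HAGH, a hydrolase of the methylglyoxal-detoxifying glyoxalase system, rose by 1.06. Ribosomal protein genes rose in 42 of 45 cases (45 adjusted over the list alone; median 0.79, adjusted p = 1.61e-10), and 3 of 21 replication-dependent histone mRNAs rose with none lower (3 and 0 adjusted over the list alone; adjusted p = 0.014). Members of both families have near-identical copies or pseudogenes, so their values are uncertain. The multimapping share was also higher in these libraries. Short genes rose as well, with a median of 0.58 in the 1902 of shortest gene span among abundant protein-coding genes. With offsets for GC content and length the histone list (median 0.03, adjusted p = 0.680) and the HSF1 list (0.0716) lost the call. The proteasome (0.45, adjusted p = 0.000271), carbonyl (0.41, 0.00397), ribosomal (0.71, 1.65e-08), replication (0.36, 0.0107) and immediate early lists (1.30, 7.53e-07) kept it. The adjusted p of all 7 lists was 0.896 with an estimated correlation, so none of the list calls held there, and over the list settings it ranged from 1.76e-14 to that value.

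NRF2 targets, the antioxidant and glutathione genes, moved in both directions, with 4 of 27 higher, 7 lower and 16 not passing (5 and 7 adjusted over the list alone; adjusted p = 0.886). The list median was 0.25 although its mean was -0.05 and its test pointed down. SLC7A11, the cystine importer, fell by 1.79 on the log2 scale, GCLC, the catalytic subunit of glutathione synthesis, fell by 1.2 and TXNRD1, a thioredoxin reductase, fell by 0.95, while NQO1 stood at 0.26 ± 0.20 (SE; adjusted p = 0.313). Stress effectors of the ATF4 pathway also split, 6 up and 4 down of 29 (7 and 5 adjusted over the list alone; adjusted p = 0.631). In that list ATF3 rose by 2.72, PPP1R15A, a phosphatase subunit that ends the translational block, rose by 2.65, and DDIT3 rose by 1.66, whereas the AP-1 repressor JDP2 fell by 1.44. Among 32 p53 targets 5 rose and 7 fell, also when adjusted over the list alone (adjusted p = 0.595), with SERTAD1 (2.45), the pro-apoptotic PMAIP1 (2.14) and GADD45A (1.52) higher and MDM2 lower. NF-kB targets and cytokines had 9 of 22 members higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.0570), including CXCL8 (2.0) and RELB (1.26). With the sample number as a block that list passed (adjusted p = 0.0487), as it did without complete 1, complete 2 or any 1 of the 3 controls (0.000513 to 0.0458). Tubulin and actin genes rose in 4 of 23 cases with none lower (4 and 0 adjusted over the list alone; adjusted p = 0.0606), led by TUBB2A (1.44). That list passed with the block (0.0166), without control 1 (0.0164) and without complete 3 (0.0220). Over the list settings the adjusted p of the NF-kB list ran from 0.000513 to 0.896 and that of the tubulin and actin list from 0.0164 to 0.896.

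The remaining lists were not called in A549 cells with complete smoke. Of 32 mitosis genes 8 fell and none rose (0 and 7 adjusted over the list alone; adjusted p = 0.499). Of 29 genes of the Fanconi anaemia and homologous recombination pathways 4 rose and 7 fell (both counts unchanged over the list alone; 0.581). Of 30 TGF-beta targets and matrix genes 2 rose and 9 fell (2 and 10 adjusted over the list alone; 0.135). HIF-1 targets had 6 of 25 higher and 4 lower (adjusted p = 0.465), among them the hypoxia-inducible ANKRD37 (3.08) and ADM (2.02). Cholesterol synthesis genes had 2 of 26 higher and 4 lower (0.581), interferon-stimulated genes 5 of 22 higher and 3 lower (0.581), and endoplasmic reticulum chaperones none of 23 higher and 3 lower (0.581), among them DNAJC3 (-1.5). None of 6 metallothioneins and zinc exporters passed (0.849), and 1 of 13 mitochondrially encoded mRNAs did (0.162, or 0.00201 without complete 1 within a range of 0.00201 to 0.983). Of 8 tested markers of other lung cell types 1 rose and 1 fell (0.581). Adjusted over the list alone, the counts of these last lists changed only for cholesterol genes (1 higher, 0 lower), chaperones (0 and 1) and mitochondrial mRNAs (0 and 0).

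The number of called genes in A549 cells with complete smoke depended on single libraries. It was 1422 without complete 2, 2003 without complete 1, and 2081, 1861 and 2278 without control 1, 2 and 3, and it was 8321 with the sample number as a block. Scaling by library size alone gave 1586 higher and 2984 lower genes, so that the share of higher genes was 34.7% in place of 47.9%, and moved the median of all genes from 0.02 to -0.10.

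Filtered smoke was compared with clean air in the same line to ask what the filtered aerosol did without the retained particles. EGR3, EGR2, HSPA6 and RGS16 were the genes with the largest rises among the named ones. EGR3 rose to 22.9 ± 10.0 CPM (6.65 ± 0.56, adjusted p = 0.000351), EGR2 rose from 0.472 ± 0.145 to 38.8 ± 12.4 CPM (6.37 ± 0.38, adjusted p = 0.000143) and HSPA6 rose to 352 ± 161 CPM (6.31 ± 0.53, adjusted p = 0.000351). RGS16, a regulator of G protein signalling, rose from 0.270 ± 0.131 to 10.5 ± 4.17 CPM (5.23 ± 0.43, adjusted p = 0.000351). HMOX1 fell to 326 ± 34.3 CPM (-2.08 ± 0.24, adjusted p = 0.000735). Among protein-coding genes that met the limits of the naming rule, the largest falls were in ZFHX3, a zinc-finger homeobox transcription factor (ENSG00000140836, chromosome 16, 72782885 to 73891871; -2.95 ± 0.40, adjusted p = 0.00121), and FBXW10B (-2.93 ± 0.39, adjusted p = 0.00112). Filtered smoke changed 7112 of 15244 genes, 3524 upward and 3588 downward (edgeR, as above), and 3215 by at least 2-fold.

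Immediate early genes rose in 24 of 32 cases and fell in 2, with the same counts adjusted over the list alone (median 1.53, camera adjusted p = 4.58e-09). Ribosomal protein genes rose in 44 of 45 (44 adjusted over the list alone; median 1.02, adjusted p = 1.37e-11). RPLP2 rose by 1.35 and RPS15 by 1.22. Proteasome subunits rose in 21 of 33 (24 adjusted over the list alone; median 0.73, adjusted p = 0.000107), for example PSMD8 (1.02). Carbonyl-metabolising enzymes rose in 15 of 30 (15 adjusted over the list alone; median 0.53, adjusted p = 0.0008), for example DCXR (1.39) and HAGH (1.26). No member of these 3 lists was lower. Among 36 replication genes 14 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.00188), with E2F1 at 1.40 and CDC45, a helicase cofactor, at 1.07. Tubulin and actin genes rose in 8 of 23 cases (7 adjusted over the list alone; adjusted p = 0.0207), a call lost without filtered 1 (0.0631) or control 3 (0.118). Replication-dependent histone mRNAs rose in 7 of 21 (7 adjusted over the list alone; adjusted p = 0.00127), H2BC21 by 1.55, with the uncertainty of near-identical copies and a multimapping share of 11.4% against 9.94% with clean air. The 1902 genes of shortest span had a median of 0.71 here. With offsets for GC content and length the histone (median 0.15, adjusted p = 0.298) and tubulin and actin lists (0.31, 0.0898) lost the call, the latter not with block and offsets together (0.0215), and the other 5 kept it. All 7 lists had an adjusted p = 0.880 with an estimated correlation and ranged from 4.18e-14 to that value over the list settings.

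NRF2 targets again moved apart, 8 of 27 higher and 7 lower (the same adjusted over the list alone; median 0.34, mean -0.06, test pointing down, adjusted p = 0.95). HMOX1, SLC7A11 (-2.29), GCLC (-1.40), GCLM (-1.22) and TXNRD1 (-1.17) fell. Of 32 p53 targets 6 rose and 13 fell (6 and 13 adjusted over the list alone; adjusted p = 0.524), with MDM2 at -2.44 and ZMAT3, an RNA-binding protein, at -2.10. HSF1 targets had 11 of 23 higher and 1 lower (the same over the list alone; adjusted p = 0.0615), a list that passed without control 1 (0.0134), filtered 1 (0.0108) or filtered 2 (0.0466) and ranged from 0.0108 to 0.880. NF-kB targets had 10 of 22 higher and 3 lower (12 and 4 adjusted over the list alone; adjusted p = 0.0939), with passing values without filtered 1 (0.0259) and filtered 2 (0.0341) in a range of 0.0259 to 0.880. Mitosis genes had 3 of 32 higher and 8 lower (2 and 8 adjusted over the list alone; adjusted p = 0.683), including the proliferation marker MKI67 (-1.45) and the kinetochore protein CENPF (-1.52). Fanconi and recombination genes had 5 of 29 higher and 10 lower (0.524), and TGF-beta and matrix genes 5 of 30 higher and 13 lower (0.228). Cholesterol genes had 8 of 26 higher and 4 lower (0.552), and endoplasmic reticulum chaperones 2 of 23 higher and 7 lower (0.552). Of 29 ATF4 targets 6 rose and 5 fell (0.628), and of 25 HIF-1 targets 8 rose and 5 fell (0.552). Of 22 interferon-stimulated genes 6 rose and 3 fell (0.651), and of 6 metallothioneins and zinc exporters 2 rose (0.524). Mitochondrially encoded mRNAs had 2 of 13 higher (0.223, or 0.0252 without filtered 1 within 0.0252 to 0.974). Of 8 markers of other lung cells 2 rose and 1 fell (0.95), among them the ciliated-cell factor FOXJ1, which rose from 0.452 ± 0.252 to 2.56 ± 0.979 CPM. Adjusted over the list alone, the counts changed for Fanconi genes (6 higher, 10 lower), TGF-beta genes (5 and 14), chaperones (2 and 5) and markers of other lung cells (1 and 1). The count of called genes was 4249 without filtered 1, 4006 without filtered 2 and 4661 without control 2. Library size alone gave 2596 higher and 4253 lower, a share of higher genes of 37.9% in place of 49.6% (median of all genes -0.15 in place of 0.01).

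The series title turns on which phase of the smoke acts, and complete and filtered smoke were therefore compared directly in A549 cells. The genes followed first are 3 fixed targets of the aryl hydrocarbon receptor (AhR), which senses polycyclic aromatic hydrocarbons. CYP1A1, a monooxygenase that oxidises such compounds (ENSG00000140465, chromosome 15, 74719542 to 74725610), measured 78.3 ± 53.7 CPM with complete smoke, 2.94 ± 0.901 with filtered smoke and 7.50 ± 9.62 with clean air (mean ± SD, n = 3). CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902) measured 676 ± 438, 86.1 ± 26.3 and 191 ± 89.3 CPM, and TIPARP, which represses the receptor, 167 ± 69.1, 59.9 ± 18.3 and 107 ± 31.0 CPM in the same order. Complete against filtered smoke, the log2 differences were 4.72 ± 0.96 (SE) for CYP1A1, 2.97 ± 0.51 for CYP1B1 and 1.48 ± 0.33 for TIPARP, but none passed over all genes (adjusted p = 0.998 each). With the sample number as a block CYP1B1 passed (2.84, adjusted p = 0.00297) and CYP1A1 (4.64, adjusted p = 0.756) and TIPARP (1.46, adjusted p = 0.167) did not. With the block BMF (1.78) and STC2 (1.55), which are not on the AhR list, differed by more than TIPARP, and neither passed. Over all settings the adjusted p ran from 2.59e-75 to 1 for CYP1A1, from 5.75e-42 to 1 for CYP1B1 and from 1.03e-09 to 1 for TIPARP, with the low ends from the fit without a low-count filter. The 10 tested AhR targets were higher as a list with complete smoke (median 0.45, 0 members past the threshold over all genes, 3 higher adjusted over the list alone, camera adjusted p = 7.90e-06). That list had an adjusted p = 0.269 with an estimated correlation and 0.0783 without filtered 3, in a range of 3.09e-08 to 0.333.

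**Figure D1:**
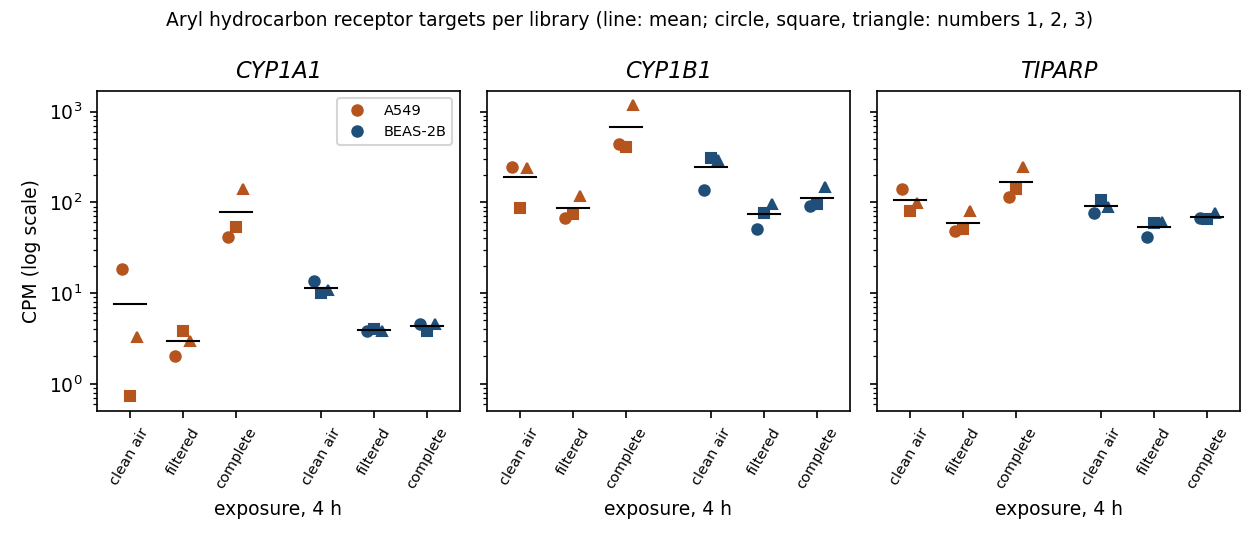
CPM (log axis) of CYP1A1, CYP1B1 and TIPARP in each library by line and exposure, with group means. In A549 cells CYP1A1 averaged 78.3 with complete and 2.94 with filtered smoke, and in BEAS-2B cells 4.31 and 3.87.

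Against clean air, CYP1A1 (3.40 ± 0.88, adjusted p = 0.0192) and CYP1B1 (1.83 ± 0.48, adjusted p = 0.0203) rose in A549 cells with complete smoke. CYP1A1 lost that call without control 3 (3.05, adjusted p = 0.0733) and CYP1B1 without control 2 (1.48, adjusted p = 0.0643), and over all settings their adjusted p reached 2.16e-46 to 0.221 and 1.53e-17 to 0.121. TIPARP stood at 0.64 (adjusted p = 0.138), or 0.58 with the block (adjusted p = 0.0496). The AhR list had 2 of 10 members higher with complete smoke, also over the list alone (adjusted p = 0.465). With filtered smoke 1 member rose and 3 fell, also over the list alone (adjusted p = 0.524). There CYP1A1 stood at -1.32 (adjusted p = 0.253), CYP1B1 at -1.15 (0.0710) and TIPARP at -0.83 (0.0547). With the block CYP1B1 (-1.08, adjusted p = 0.00384) and TIPARP (-0.88, adjusted p = 0.00554) passed, and without control 2 so did CYP1B1 (-1.49, adjusted p = 0.0352). Over all settings these adjusted p values ran from 1.94e-07 to 0.195 for CYP1B1 and from 0.000281 to 0.198 for TIPARP.

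Over the whole of A549 expression, no gene passed between complete and filtered smoke. None of 15244 genes passed in edgeR, while 236 had an unadjusted p under 0.05. DESeq2 called 3 genes, limma-voom called 0, edgeR without a low-count filter called 19 and with the block 1. The 95% interval of the difference lay within 2-fold for 77.0% of genes, and for 86.5% with the block. Ribosomal proteins (median -0.22, adjusted p = 2.63e-06) and histone mRNAs (median -0.21, adjusted p = 0.00336) were lower as lists with complete smoke, with no member past the threshold over all genes or over the list alone, and both are uncertain for shared copies. Each had an adjusted p = 0.933 with an estimated correlation. The ribosomal call was lost without filtered 1 (0.526) or complete 3 (0.603), and the histone call without filtered 1 (0.152) and with the offsets (0.0902), in ranges of 7.57e-13 to 0.993 and 5.89e-05 to 0.993. The tubulin and actin list (0.0551) passed with the block (0.00256), with library size alone (0.0378) and without complete 1 (0.00259), complete 2 (0.0388) or filtered 3 (0.00327), in a range of 0.00256 to 0.993. Other lists that did not pass with all libraries did so in some settings. Metallothioneins passed without complete 3 (0.000233) or filtered 2 (9.20e-05), and with library size alone (0.0378). Immediate early genes passed without complete 2 (0.0286), complete 3 (0.000233) or filtered 1 (3.09e-08), and p53 targets without complete 1 (0.000527) or filtered 2 (0.000141). Without complete 1, complete 2 and filtered 3 in turn, the proteasome list gave 0.0136, 0.0286 and 0.000947, the replication list 0.0023, 0.0427 and 0.00951, and the carbonyl list 0.0199, 0.0427 and 0.0108. The HSF1 list passed without filtered 1 (0.0238), the NF-kB list without complete 1 (0.0136) or complete 3 (0.000233), and mitochondrial mRNAs without complete 1 (0.0167), complete 3 (0.0463) or filtered 1 (0.0238). Without complete 1 the NF-kB and mitochondrial lists pointed the other way than with all libraries. With block and offsets the p53 (0.0258), replication, proteasome (0.0276 each) and mitosis lists (0.0497) passed. Over the list settings these 10 lists ranged from 3.09e-08 to 0.993.

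Fold changes with complete and with filtered smoke followed each other closely in A549 cells. Across 15244 genes, which are not independent replicates, they correlated at r = 0.953 and rho = 0.957 and had the same sign for 93.0% of genes. Unchanged groups simulated against the same controls gave r = 0.497 and 66.5%, and the covariance was 0.633 against a simulated 0.0453 (20 simulations). Of the called genes 2237 rose and 2464 fell in both comparisons and 0 moved in opposite directions, where independent lists would share 548 and 607. The 3 controls are too few to split, so part of the excess may come from sharing them. The simulated groups also carried no effect of the shared sample numbers, which could raise these values. The response score, which averages the change of 7646 responding genes in the direction of the joint response, was 0.844 ± 0.212 with complete and 0.994 ± 0.268 with filtered smoke (SD, n = 3; 2-sided exact permutation p = 0.5), and was lower with complete smoke in 3 of 3 sample numbers.

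**Figure D2:**
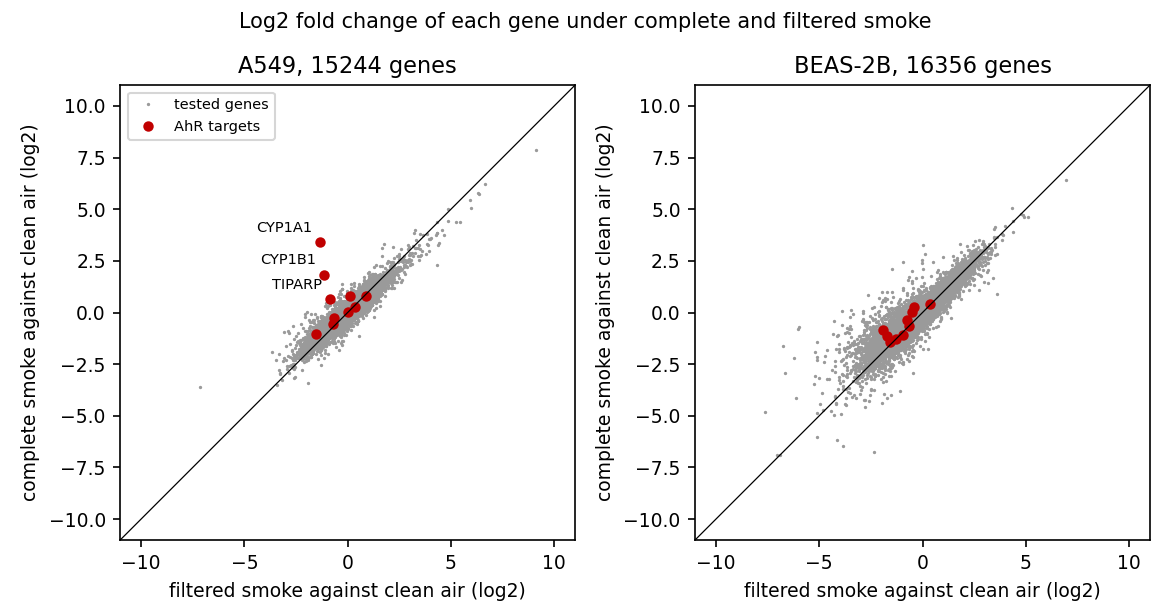
Log2 fold change against clean air with complete smoke (vertical) and filtered smoke (horizontal), 1 point per gene, in A549 (left) and BEAS-2B cells (right). Points lie along the diagonal (r = 0.953 and 0.939), and CYP1A1 and CYP1B1 lie off it in A549 cells.

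**Figure D3:**
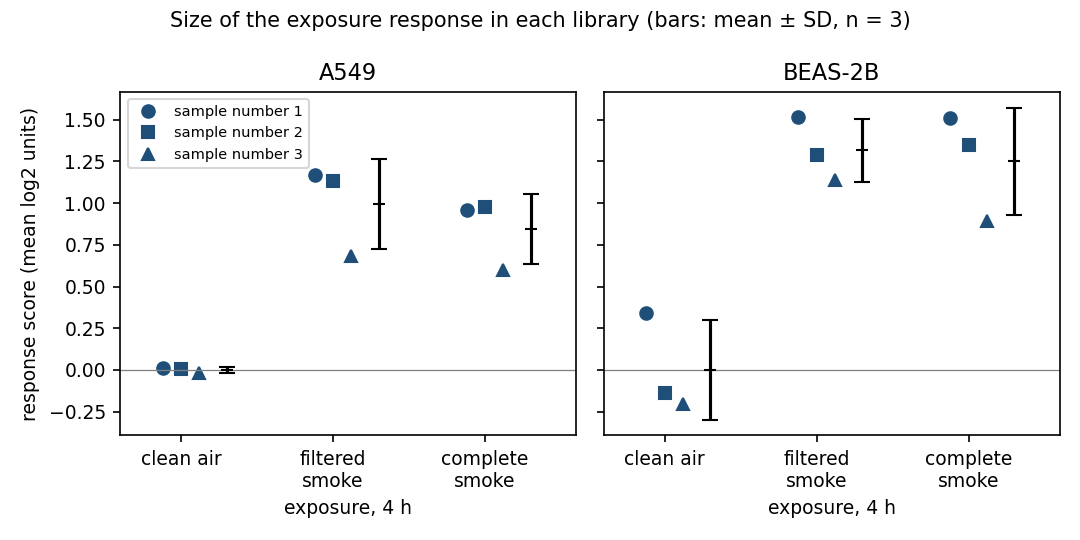
Response score of each library (mean signed log2 change from the mean of the clean-air libraries over responding genes) by line and exposure, numbered by sample number. In A549 cells the exposed libraries numbered 3 lie at 0.600 and 0.685, below the others of their groups.

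In BEAS-2B cells complete smoke was compared with clean air to ask the same of bronchial cells. FOS, an AP-1 subunit (ENSG00000170345, chromosome 14, 75278774 to 75282230), rose from 4.27 ± 5.06 to 114 ± 46.0 CPM (mean ± SD, n = 3; 4.73 ± 0.81, adjusted p = 0.00397). The inflammatory cytokine IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002) rose from 3.58 ± 1.59 to 36.0 ± 18.4 CPM (3.34 ± 0.44, adjusted p = 0.00213), and the neutrophil attractant CXCL8 from 17.3 ± 4.73 to 104 ± 38.7 CPM (2.58 ± 0.31, adjusted p = 0.0017). BMF, a pro-apoptotic BH3-only protein (ENSG00000104081, chromosome 15, 40087890 to 40108892), fell from 58.9 ± 4.62 to 2.18 ± 1.12 CPM (-4.75 ± 0.40, adjusted p = 0.00124). Of 16356 genes 6704 passed, 3517 higher and 3187 lower (edgeR, as above), and 4887 changed at least 2-fold.

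Cytokines and other NF-kB targets rose in 17 of 27 cases and fell in 1 (19 and 1 adjusted over the list alone; median 1.59, camera adjusted p = 2.76e-05), with IL1B at 2.82 and the monocyte attractant CCL2 at 2.84. Immediate early genes rose in 20 of 32 with none lower (21 adjusted over the list alone; median 1.47, adjusted p = 1.69e-07), with EGR2 at 2.83 and IER2 at 2.35. Proteasome subunits rose in 20 of 33 and fell in 1 (21 and 1 adjusted over the list alone; median 0.88, adjusted p = 2.76e-05), POMP, the proteasome assembly factor, by 1.64. Tubulin and actin genes rose in 16 of 24 (17 adjusted over the list alone; median 0.89, adjusted p = 0.000124), MYL12A by 1.93 and ACTG1 by 1.71. Ribosomal proteins rose in 44 of 45 (44 adjusted over the list alone; median 1.83, adjusted p = 4.70e-15), and replication-dependent histone mRNAs in 44 of 44 (44 adjusted over the list alone; median 2.19, adjusted p = 1.51e-17), H1-4 by 4.05. The last 2 families hold near-identical copies and are uncertain, in libraries whose multimapping share was 18.3% (31.7% in library 3) against 8.50% with clean air. Carbonyl-metabolising enzymes rose in 12 of 30 and fell in 2 (the same over the list alone; median 0.35, adjusted p = 0.0207), HAGH by 2.02 and GSTO1 by 1.90. Scaling by library size alone put their median at -0.31 (adjusted p = 0.152), a move of about the size of the one it gave the median of all genes. The call was lost without control 3 (0.0733) and with the offsets (median 0.57, adjusted p = 0.0569), where the other 6 lists kept theirs, beside a median of 0.96 in the 1686 genes of shortest span. With an estimated correlation the carbonyl list had an adjusted p = 0.662 and the other 6 lists an adjusted p = 0.612, and over the list settings the 7 lists ranged from 7.55e-28 to 0.662.

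Protein-folding genes of the endoplasmic reticulum included 8 of 24 that fell and 1 that rose (the same over the list alone; adjusted p = 0.183), with the chaperone HSPA5 at -1.52, its cofactor DNAJC3 at -2.23 and SEL1L, a subunit of the degradation machinery, at -2.04. AhR targets had 4 of 10 lower and none higher (also over the list alone; adjusted p = 0.146). CYP1A1 fell from 11.5 ± 1.81 to 4.31 ± 0.405 CPM (-1.41 ± 0.20, adjusted p = 0.00228). Mitosis genes had 2 of 33 higher and 12 lower (2 and 12 over the list alone; adjusted p = 0.0563), including the spindle motor KIF11 (-1.70), a list that passed without control 1 (0.0294) or complete 2 (0.0280) and with the offsets (0.0225) in a range of 0.00505 to 0.662. Of 32 p53 targets 11 rose, GADD45A by 2.33 and the kinase PLK3 by 2.23, and 7 fell (adjusted p = 0.388). NRF2 targets had 6 of 28 higher, thioredoxin TXN among them (1.77), and 1 lower (5 and 0 adjusted over the list alone; adjusted p = 0.273), and HMOX1 stood at -0.23 ± 0.58 (SE; adjusted p = 0.764). ATF4 targets had 5 of 29 higher and 1 lower (0.391), with ATF3 at 2.07 and TRIB3 at 1.49, and HSF1 targets 3 of 23 higher and 1 lower (0.602). TGF-beta targets and matrix genes had 9 of 30 higher and 5 lower (0.457), and HIF-1 targets 10 of 26 higher and 5 lower (0.710). Cholesterol genes had 7 of 26 higher and 4 lower (0.446), and replication genes 6 of 36 higher and 5 lower (0.710). Fanconi and recombination genes had 4 of 29 higher and 9 lower (0.238), and interferon-stimulated genes 6 of 27 in each direction (0.710). Metallothioneins had 2 of 9 higher (0.702), and mitochondrially encoded mRNAs 4 of 13 higher and 1 lower (0.171). Of 12 markers of other lung cells 1 rose and 4 fell (0.282), among them the fibroblast receptor PDGFRB (-2.43) and the mucin MUC5AC. Adjusted over the list alone, the counts changed for TGF-beta genes (9 higher, 6 lower), HIF-1 targets (11 and 6), replication genes (5 and 5) and mitochondrial mRNAs (3 and 1). With fry, which tests whether a list moves on balance one way and does not compare it with other genes, 7 of these lists passed. They were the AhR (0.00371), chaperone, Fanconi (0.0419 each) and other lung cell lists (0.00287), which pointed down, and the TGF-beta (0.00745), mitochondrial (0.0302) and p53 lists (0.0326), which pointed up. NRF2 targets passed without both control 1 and complete 3 (0.0446), and over the list settings these 8 lists ranged from 0.00287 to 0.909. MUC5AC was carried by 1 count over the 3 exposed libraries against 193 over the controls, a ratio of 0.00623 with a 95% exact Poisson interval of 0.000157 to 0.0351 for counting error only.

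**Figure D4:**
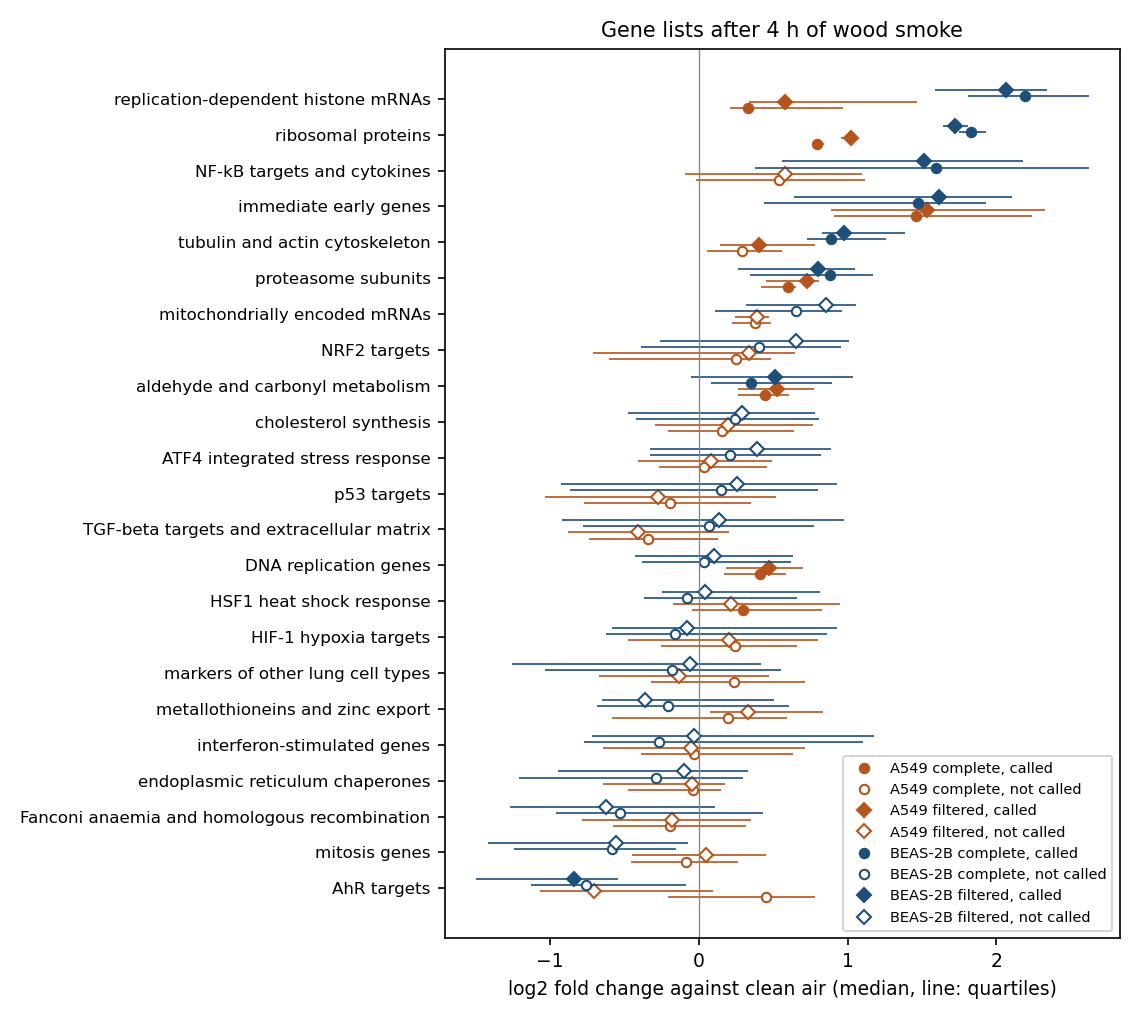
Median log2 fold change of each gene list fixed before the data were examined, for complete and filtered smoke against clean air in both lines, with filled symbols where the camera test passed at the preset correlation. Ribosomal protein genes had medians of 0.79 and 1.02 in A549 cells and 1.83 and 1.72 in BEAS-2B cells.

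The count of called genes in BEAS-2B cells with complete smoke was 3600 and 3757 without complete 1 and 2, and 2991 and 2916 without control 2 and 3. Control 1 stood apart from the other BEAS-2B controls, with a chi-square per degree of freedom of 211 and 228 against them where they differed by 8.94, and without it the count was 8298. Library size alone turned most calls downward, with 1531 genes higher and 6835 lower (18.3% higher in place of 52.5%), as the median of all genes moved from -0.06 to -0.75, so the directions in this line are relative to the bulk of genes.

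Filtered smoke in BEAS-2B cells was set against the same controls. FOS rose to 124 ± 32.5 CPM (4.85 ± 0.81, adjusted p = 0.004) and IL6 to 27.9 ± 2.86 CPM (2.97 ± 0.43, adjusted p = 0.00283), and RGS2, a regulator of G protein signalling, rose from 3.14 ± 0.487 to 35.2 ± 15.7 CPM (3.49 ± 0.45, adjusted p = 0.00241). SNAI1, a repressor of E-cadherin, rose from 2.77 ± 0.582 to 26.2 ± 9.95 CPM (3.24 ± 0.43, adjusted p = 0.00241). BMF fell to 2.71 ± 0.907 CPM (-4.45 ± 0.39, adjusted p = 0.00161), and TGFBR3, a TGF-beta co-receptor, fell from 24.4 ± 9.71 to 2.48 ± 0.240 CPM (-3.29 ± 0.43, adjusted p = 0.00241). In total 7947 of 16356 genes passed, 3867 higher and 4080 lower (edgeR, as above), and 5877 changed at least 2-fold.

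As with complete smoke, NF-kB targets (18 of 27 higher, 1 lower, the same over the list alone; median 1.51, camera adjusted p = 7.44e-05), immediate early genes (22 of 32 higher, 23 adjusted over the list alone; median 1.61, adjusted p = 1.34e-08) and tubulin and actin genes (17 of 24 higher, 18 adjusted over the list alone; median 0.98, adjusted p = 2.76e-05) rose. RELB (2.75), IL1B (2.63) and CXCL8 (1.89) were among the NF-kB targets. Proteasome subunits rose in 20 of 33 cases and fell in 1 (21 and 2 adjusted over the list alone; median 0.80, adjusted p = 9.78e-05). Ribosomal proteins rose in 44 of 45 (44 adjusted over the list alone; median 1.72, adjusted p = 1.91e-13) and histone mRNAs in 43 of 44 (44 adjusted over the list alone; median 2.07, adjusted p = 1.52e-15), again uncertain for shared copies, beside a multimapping share of 13.9%. AhR targets fell, with 6 of 10 lower and none higher (also over the list alone; median -0.84, adjusted p = 0.025). CYP1A1 fell to 3.87 ± 0.108 CPM (-1.57 ± 0.20, adjusted p = 0.00231) and CYP1B1 from 247 ± 96.1 to 73.8 ± 22.6 CPM (-1.74 ± 0.37, adjusted p = 0.00762). Carbonyl-metabolising enzymes rose in 14 of 30 and fell in 3 (14 and 4 adjusted over the list alone; median 0.51, adjusted p = 0.0282), and library size alone, which moved the median of all genes by about as much, put their median at -0.12 (adjusted p = 0.114). That call was lost without control 2 (0.0522) or control 3 (0.0769) and with the offsets (0.0520), where the other 7 lists kept theirs, beside a median of 1.02 in the 1686 genes of shortest span. With an estimated correlation the ribosomal, proteasome and carbonyl lists had an adjusted p = 0.646 and the other 5 called lists an adjusted p = 0.616, and over the list settings the 8 lists ranged from 1.29e-24 to 0.646.

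Mitosis genes had 2 of 33 higher and 16 lower (also over the list alone; adjusted p = 0.0640), MKI67 at -1.81 and CENPF at -2.0. This list passed with the block (0.00726), with block and offsets (0.0224) and without control 1 (0.0359) or filtered 3 (0.0251), in a range of 0.00726 to 0.677. Mitochondrially encoded mRNAs had 6 of 13 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0669, or 0.0244 with the block and 0.0338 without filtered 1, in a range of 0.0124 to 0.629). The one that fell, MT-ND6, is encoded on the opposite strand to the others. NRF2 targets had 12 of 28 higher and 2 lower (also over the list alone; 0.0745), passing without control 1 (0.0359) or filtered 1 (0.0306) in a range of 0.0239 to 0.646. ATF4 targets had 8 of 29 higher and 1 lower (0.153) and HSF1 targets 7 of 23 higher and 1 lower (0.304), and both passed without filtered 1 (0.0432 and 0.0338, in ranges of 0.0432 to 0.705 and 0.0338 to 0.762). Of 24 chaperones of the endoplasmic reticulum 8 fell and 1 rose (0.304), of 32 p53 targets 11 rose and 8 fell (0.370), and of 29 Fanconi and recombination genes 4 rose and 12 fell (0.117). HIF-1 targets had 12 of 26 higher and 9 lower (0.568), and TGF-beta and matrix genes 10 of 30 higher and 6 lower (0.435). Cholesterol genes had 8 of 26 higher and 6 lower (0.356), and replication genes 10 of 36 higher and 7 lower (0.518). Interferon-stimulated genes had 7 of 27 higher and 5 lower (0.748), metallothioneins 2 of 9 higher (0.748), and markers of other lung cells 1 of 12 higher and 3 lower (0.435). Adjusted over the list alone, the counts were 6 higher and 1 lower for ATF4 targets, 5 and 1 for HSF1 targets, 1 and 6 for chaperones, 5 and 14 for Fanconi genes and 12 and 10 for HIF-1 targets. They were 10 and 8 for TGF-beta genes, 10 and 5 for replication genes, 6 and 3 for interferon-stimulated genes and 1 and 0 for metallothioneins. With fry the Fanconi (0.0166) and other lung cell lists (0.00356) passed downward and the TGF-beta (0.00403), p53 (0.0234) and cholesterol lists (0.0348) upward, and over the list settings these 5 ranged from 0.00356 to 0.818. The count of called genes was 4735 and 4513 without filtered 1 and 2, and 3799 and 3652 without control 2 and 3. Library size alone gave 1663 higher and 7415 lower genes (18.3% higher in place of 48.7%), with the median of all genes at -0.74 in place of -0.07.

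Complete and filtered smoke were then compared directly in BEAS-2B cells. CYP1A1 measured 4.31 ± 0.405 CPM with complete and 3.87 ± 0.108 with filtered smoke (log2 difference 0.16 ± 0.20, adjusted p = 1), CYP1B1 112 ± 32.0 and 73.8 ± 22.6 CPM (0.61 ± 0.36, adjusted p = 1), and TIPARP 69.5 ± 5.84 and 53.6 ± 10.6 CPM (0.37 ± 0.21, adjusted p = 1). The 10 AhR targets were higher as a list with complete smoke (median 0.27, no member past the threshold over all genes or over the list alone, camera adjusted p = 0.0200), with an adjusted p = 0.370 with an estimated correlation and a range of 0.000795 to 0.370. Without complete 1 (0.0987), filtered 1 (0.0668) or filtered 3 (0.0987) that call was lost. None of 16356 genes passed in edgeR, with 222 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom, and leaving out complete 2 gave 2. The 95% interval lay within 2-fold for 58.3% of genes, and for 75.1% with the block.

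A further 5 lists were lower with complete than with filtered smoke at the preset correlation, each with a small median, no member past the threshold over all genes or over the list alone, and an adjusted p = 0.882 with an estimated correlation. They were immediate early genes (-0.13, adjusted p = 0.0200), NRF2 targets (-0.14, 0.0444), ATF4 targets (-0.11, 0.0444), interferon-stimulated genes (-0.08, 0.0444, or 0.0765 with the block) and tubulin and actin genes (-0.10, 0.04996). All 5 lost the call without complete 3, at an adjusted p of 0.424, 0.926, 0.725, 0.360 and 0.690 in that order, and the ATF4 and tubulin and actin lists also changed direction there. The first 3 also lost it without complete 1 (0.0987, 0.124 and 0.0987), filtered 2 (0.263, 0.576 and 0.665) or filtered 3 (0.0635, 0.148 and 0.0635). The interferon list lost it without complete 2 (0.308) or filtered 3 (0.734), and the tubulin and actin list without filtered 1 (0.578) or filtered 2 (0.244). With the offsets the immediate early (0.619), ATF4 (0.276) and tubulin and actin lists (0.571) also lost it. Over the list settings the 5 lists ranged from 0.000662 to 0.974. Other lists passed in some settings only. HSF1 targets (0.0512) passed without filtered 1 (3.22e-07) or complete 2 (0.00267) and with the offsets (0.0248). Ribosomal proteins (0.210) passed without filtered 1 (0.000416) or complete 3 (3.07e-05), with library size alone (0.0350), with the offsets (0.00972) and without both control 1 and complete 3 (1.26e-10). NF-kB targets (0.00675) and proteasome subunits (0.0385) passed without complete 3, the latter also without control 1 and complete 3 together (0.00557). Mitochondrial mRNAs (0.181) passed with the offsets (0.00972), chaperones and mitosis genes without filtered 1 (0.00385 each), and histone mRNAs without complete 2 (0.0167) or filtered 3 (0.00628). Over the list settings these 8 lists ranged from 1.26e-10 to 0.998.

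Fold changes with complete and filtered smoke correlated at r = 0.939 and rho = 0.955 across genes in BEAS-2B cells, against r = 0.497 in simulated unchanged groups, with a covariance of 1.26 against 0.0837 and the same sign in 93.0% of genes against 66.6%. In both comparisons 3259 genes rose and 2861 fell and 0 moved in opposite directions, where independent lists would share 832 and 795. Part of the excess may again come from the shared controls or the shared sample numbers. The response score over 9019 genes was 1.25 ± 0.322 with complete and 1.32 ± 0.190 with filtered smoke (SD, n = 3; 2-sided exact permutation p = 0.8).

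The last comparison tested whether the responses differed between the lines, as the fold change in BEAS-2B minus that in A549 cells. With complete smoke NRG1, a growth factor of the ERBB receptors (ENSG00000157168, chromosome 8, 31639386 to 32767959), responded more in the upward direction in BEAS-2B cells (difference 2.27 ± 0.23, adjusted p = 0.000388, n = 3 per group). CCNE1, cyclin E1 (-1.70 ± 0.29, adjusted p = 0.0084), NRARP, a Notch pathway regulator (-3.03 ± 0.43, adjusted p = 0.00303), AMH (-3.09 ± 0.43, adjusted p = 0.00303) and BMF (-4.51 ± 0.56, adjusted p = 0.0013) differed in the other direction. In total 308 of 17703 genes differed, 100 with a higher and 208 with a lower fold change in BEAS-2B cells (edgeR interaction test), and 3070 had an unadjusted p under 0.05. CYP1A1 (-4.80 ± 0.97, adjusted p = 0.0217) and CYP1B1 (-3.005 ± 0.65, adjusted p = 0.0267) were among those with the lower fold change. CYP1A1 lost the call when 1 of 4 libraries was left out and CYP1B1 when 1 of 8 was (highest adjusted p of 0.0634 and 0.0767, both without A549 complete 3), and over all settings they ranged from 2.67e-29 to 0.0634 and from 7.08e-14 to 0.0767. Of the 29 genes that the naming rule gave here 7 kept the call whichever library was left out.

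Histone mRNAs (median 1.57, 5 higher, 19 adjusted over the list alone, camera adjusted p = 2.14e-20) and ribosomal proteins (1.06, adjusted p = 7.81e-15), both uncertain for shared copies, had the higher fold change in BEAS-2B cells, as did NF-kB targets (0.78, 1 higher and 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.000214) and tubulin and actin genes (0.63, adjusted p = 0.00159). Mitosis genes (-0.53, adjusted p = 0.00777), DNA replication genes (-0.31, adjusted p = 0.00777) and AhR targets (-0.68, 2 lower, 3 over the list alone, adjusted p = 0.0284) had the lower fold change. With an estimated correlation the histone list had an adjusted p = 0.0953, the AhR list 0.545 and the other 5 lists 0.619. The mitosis call was lost without A549 complete 1 (0.0618) or A549 control 2 (0.0521). The replication call was lost without A549 complete 1 (0.0800), BEAS-2B control 1 (0.0615) or BEAS-2B complete 3 (0.0820). The AhR call was lost without BEAS-2B control 1 (0.0506) or BEAS-2B complete 3 (0.0602) and with library size alone (0.0566). The p53 list (0.30, 2 higher, adjusted p = 0.0225) and the TGF-beta list (0.34, 2 higher, 3 and 1 adjusted over the list alone, adjusted p = 0.0124) were higher too, with medians of -0.27 and -0.15 under library size alone (adjusted p = 0.0506 and 0.0164), which moved the median of all genes by about as much. With an estimated correlation their adjusted p was 0.619 and 0.545. The p53 call was lost without A549 complete 1 (0.202) or A549 control 2 (0.0817), and the TGF-beta call without A549 control 1 (0.0528), A549 complete 2 (0.0704) or BEAS-2B control 1 (0.0659). Markers of other lung cells (-1.06, 1 lower, adjusted p = 0.0412) had an adjusted p = 0.311 with an estimated correlation and lost the call with the block (0.0843), with library size alone (0.116) and without A549 complete 1 (0.0714), A549 control 2 (0.0889), BEAS-2B control 1 (0.0659), BEAS-2B control 2 (0.0523) or BEAS-2B complete 3 (0.151). The offsets changed none of these 10 calls, and over the list settings they ranged from 2.72e-24 to 0.619. Fanconi genes, chaperones, proteasome subunits, HSF1 targets and NRF2 targets did not pass with all libraries and passed without 1 to 4 single libraries. Fanconi genes passed with the block (0.0403) or library size alone (0.0353) too, proteasome subunits with the block (0.04), and chaperones with block and offsets (0.0431). The 5 ranged from 0.00378 to 0.841 over the list settings.

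The count of genes that differed with complete smoke moved with nearly every library. It was 170, 186 and 97 without A549 complete 1, 2 and 3, and 101, 87 and 114 without A549 control 1, 2 and 3. It was 96, 175 and 564 without BEAS-2B complete 1, 2 and 3, and 797, 144 and 134 without BEAS-2B control 1, 2 and 3. Library size alone gave 45 higher and 1526 lower genes (2.86% higher in place of 32.5%; median of all genes -0.56 in place of -0.03).

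With filtered smoke the lines differed for 146 of 17703 genes, 55 higher and 91 lower in BEAS-2B cells (edgeR interaction test; 2449 at an unadjusted p under 0.05). NRG1 (2.06 ± 0.23, adjusted p = 0.00103) and RAP1GAP2 (1.99 ± 0.32, adjusted p = 0.0084) had the higher fold change in BEAS-2B cells, and CCNE1 (-1.65 ± 0.29, adjusted p = 0.0115) and NRARP (-3.57 ± 0.43, adjusted p = 0.00103) the lower. Of the 22 genes that the naming rule gave here 9 kept the call whichever library was left out. Higher as lists were histone mRNAs (1.06, 1 higher, 8 adjusted over the list alone, camera adjusted p = 1.42e-14) and ribosomal proteins (0.74, adjusted p = 1.01e-09), both uncertain for shared copies, NF-kB targets (0.89, adjusted p = 0.000134) and tubulin and actin genes (0.59, adjusted p = 0.000536). Lower were mitosis genes (-0.53, adjusted p = 0.000536), replication genes (-0.27, adjusted p = 0.00132) and Fanconi and recombination genes (-0.26, adjusted p = 0.0118). The p53 (0.52, 2 higher, 6 adjusted over the list alone, adjusted p = 0.00100), TGF-beta (0.47, adjusted p = 0.00565) and NRF2 lists (0.40, adjusted p = 0.00864) were higher too. They kept the call with library size alone, under which their medians were -0.01, -0.10 and -0.13 as the median of all genes moved by about as much, and the NRF2 call was lost without A549 filtered 3 (0.0590). With an estimated correlation the histone list had an adjusted p = 0.266, the TGF-beta list 0.586, the replication list 0.596 and the other 7 lists 0.593, and over the list settings the 10 lists ranged from 2.70e-19 to 0.596. The offsets changed none of these 10 calls. ATF4 targets passed only without A549 filtered 2 (0.0342), BEAS-2B control 1 (0.0286) or BEAS-2B filtered 1 (0.0164), AhR targets only without A549 control 1 (0.0376), proteasome subunits only without BEAS-2B control 1 (0.0217) and markers of other lung cells only with fry (0.0103), which does not compare a list with other genes, in a range of 0.0103 to 0.992.

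The count with filtered smoke was 54, 48 and 67 without A549 control 1, 2 and 3, 95, 70 and 71 without A549 filtered 1, 2 and 3, 65, 47 and 86 without BEAS-2B filtered 1, 2 and 3, and 73 and 63 without BEAS-2B control 2 and 3, and it was 2742 with the sample number as a block. Library size alone gave 28 higher and 794 lower genes (3.41% higher in place of 37.7%; median of all genes -0.55 in place of -0.03).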

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

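The split tests reported in this part were planned, and no tests here were chosen only after the result was seen.

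Responses that differed between the lines were picked out because the edgeR interaction test passed. All are BEAS-2B minus A549 on the log2 scale, and line cannot be told apart from sample series. With complete smoke 308 genes differed. The higher ones among the named genes were ZBTB20 (3.20), H2AC14 (3.03), TMEM92 (2.50), ID3 (2.39), H2AC13 (2.37), WNT5B (2.36), NRG1 (2.27), SIPA1L3 (2.18), H3C2 (2.03), TRAF1 (1.93), PLK3 (1.86), H3C10 (1.67) and FBXO22 (0.97). The lower ones were ALDH3A2 (-0.997), VEGFA (-1.09), TNFAIP2 (-1.42), KLF4 (-1.43), CCNE1 (-1.70), STC2 (-1.90), EGR2 (-2.90), TSPYL2 (-2.99), CYP1B1 (-3.005), NRARP (-3.03), AMH (-3.09), BMF (-4.51), EGR3 (-4.52), CYP1A1 (-4.80) and MUC5AC (-6.59). The histone genes H2AC14, H2AC13, H3C2 and H3C10 have near-identical copies and are uncertain, and MUC5AC rests on 1 count in the exposed BEAS-2B libraries. Of the 29 genes that the naming rule gave here 22 lost the call without at least 1 library (highest adjusted p = 0.221).

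With filtered smoke 146 genes differed. The higher ones were TMEM92 (2.43), NOPCHAP1 (2.15), NRG1 (2.06), CFAP251 (2.02), RAP1GAP2 (1.99), PLK3 (1.97), TRAF1 (1.91), DUSP4 (1.69), H3C10 (1.53) and FBXO22 (1.03). The lower ones were KLF4 (-1.30), CCNE1 (-1.65), ANKRD37 (-2.44), ACSM3 (-2.94), TUB (-2.99), ADAMTS1 (-3.42), EGR2 (-3.55), NRARP (-3.57), MT-ND6 (-4.02), EGR3 (-4.89) and MUC5AC (-6.36, again on 1 count). Of the 22 genes that the naming rule gave here 13 lost the call without at least 1 library (highest adjusted p = 0.158).

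List medians that differed with complete smoke were AhR targets (-0.68), p53 targets (0.30), NF-kB targets (0.78), mitosis genes (-0.53), DNA replication genes (-0.31), TGF-beta targets (0.34), tubulin and actin genes (0.63), ribosomal proteins (1.06), histone mRNAs (1.57) and markers of other lung cells (-1.06). With filtered smoke they were NRF2 targets (0.40), p53 targets (0.52), NF-kB targets (0.89), mitosis genes (-0.53), DNA replication genes (-0.27), Fanconi and recombination genes (-0.26), TGF-beta targets (0.47), tubulin and actin genes (0.59), ribosomal proteins (0.74) and histone mRNAs (1.06). None of these 20 list calls held with an estimated correlation.

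Multimapping reads, which the comparisons do not use, took a larger share in the exposed than in the control libraries, at 11.3% and 11.4% in A549 cells with complete and filtered smoke and 18.3% ± 11.7 and 13.9% ± 4.59 (SD, n = 3) in BEAS-2B cells. The 18.3% is carried largely by library 3 (31.7%, where the others held 12.9% and 10.2%).

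Splitting the libraries of each line difference in other ways gave as many genes in 3 of 50 splits with complete smoke (308 against a highest other of 6397) and in 5 of 50 with filtered smoke (146 against 2163), the real split included, and splits that swap exposed and control in a single line add both responses together. For comparisons of 3 against 3 libraries, 10 splits are too few to exclude chance. The real count and the highest other were 4951 and 0 for A549 complete smoke, 7112 and 0 for filtered smoke, 6704 and 889 for BEAS-2B complete smoke and 7947 and 0 for filtered smoke, so 1 of 10 splits reached the real count in each. Complete against filtered smoke gave 0 genes with the real split, with a highest other of 3162 in A549 and 0 in BEAS-2B cells. Any split reaches a count of 0, so the 10 of 10 splits that did cannot tell whether complete and filtered smoke differ.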

How the results depend on the processing

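The tests of lists with offsets, and those with counts that ignore strand, library size alone, sample numbers 1 and 2 only, and BEAS-2B without control 1 and complete 3 were chosen only after the result was seen.

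Counts of called genes that moved over 1.5 times are grouped by setting, and the cause was not tested. A count that stayed can hold other genes. With the offsets A549 complete smoke gave 4505 genes, 3231 of them among the 4951, and filtered smoke 6255, with 4656 of the 7112 and 20 of these with the other sign. BEAS-2B complete smoke gave 7741, with 5664 of the 6704, and filtered smoke 8144, with 6253 of the 7947 and 18 with the other sign. The offsets ended 68 calls of named genes and added 17. A549 complete smoke against control (4951) gave 8321 with the sample number as a block, 7507 with block and offsets, 2574 with all 18 libraries in one fit, 8913 with numbers 1 and 2 only and 1887 at 2-fold or more, and filtered smoke (7112) gave 3215 at 2-fold or more. A549 complete against filtered smoke (0) gave 19 with no low-count filter, 3 with DESeq2, 1 with the block, 1 with block and offsets and 37 with numbers 1 and 2 only. BEAS-2B complete smoke against control (6704) gave 10616 without control 1 and complete 3, and filtered smoke (7947) gave 5264 with numbers 1 and 2 only. Numbers do not pair BEAS-2B complete and control samples (r of 0.854, -0.303 and 0.860, with number 2 not best with its own number), and the block moved that count to 10315. Line differences with complete (308) and filtered smoke (146) gave 797 and 450 with no low-count filter, 900 and 645 with DESeq2, 3541 and 2742 with the block, 859 and 533 with offsets, 4336 and 3400 with block and offsets, and 1571 and 822 with library size alone.

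Leaving out each library in turn gave 1422 to 6805 genes for A549 complete smoke, 4006 to 9015 for filtered smoke and 0 for complete against filtered, 2916 to 9026 for BEAS-2B complete smoke, 3652 to 9276 for filtered smoke and 0 to 2 for complete against filtered, and 87 to 797 and 47 to 182 for the line differences. The correlation of complete and filtered responses ran from 0.910 to 0.952 in A549 and 0.882 to 0.946 in BEAS-2B cells. For lists that changed direction, adjusted p ran from 0.000233 to 0.883 (NF-kB) and 0.0167 to 0.702 (mitochondrial) in A549 complete against filtered, with values of 0.0136 and 0.0167 without complete 1, and from 0.000662 to 0.725 (ATF4) and 0.0119 to 0.690 (tubulin and actin) in BEAS-2B, with values of 0.725 and 0.690 without complete 3. In the same BEAS-2B comparison the interferon list changed direction with numbers 1 and 2 only (0.784), and the NRF2 (0.918), ATF4 (0.624) and tubulin and actin lists (0.624) without control 1 and complete 3. With block and offsets MT2A (-0.38) and TRIB3 (-0.36) changed direction in A549 filtered smoke.

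Over settings other than leaving out a library, 1493 list results stayed, 50 were gained, 132 lost and 4 reversed, and 9412 gene results stayed, 327 were gained, 288 lost and 2 reversed. Leaving out a library kept 1252 list results, gained 75, lost 49 and reversed 4, and kept 4435 gene results, gained 30 and lost 809. At least 1 library left out ended the call of 49 of the 92 genes that the naming rule gave for A549 complete smoke and passed, 28 of 100 for filtered smoke, 39 of 103 for BEAS-2B complete smoke and 40 of 107 for filtered smoke (highest adjusted p of 0.167, 0.182, 0.165 and 0.142). An estimated correlation ended all 58 list calls, and fry, which tests whether a list moves and not whether it differs from other genes, missed 38 of them and passed 14 others. The offsets ended 10 and added 4, and with the block 7 and 13. Apart from the values given beside the results, the block changed no other call reported for the paired comparisons.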

Other observations

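The tests of the AhR targets, of the libraries numbered 3, of transcript length and of counts that ignore strand were chosen only after the result was seen.

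With clean air the lines differed widely, where line again cannot be told apart from sample series. In these controls 9799 genes differed, 4837 higher in BEAS-2B and 4962 higher in A549 cells. NRF2 targets were lower in BEAS-2B cells (median -1.87, 1 higher and 22 lower, adjusted p = 9.06e-07), as were p53 targets (-2.06, 1 higher and 25 lower, adjusted p = 9.06e-07). Ribosomal proteins (1.31, 39 higher and 0 lower, adjusted p = 9.06e-07), proteasome subunits (1.03, 24 and 1, adjusted p = 3.13e-05), DNA replication genes (1.02, 27 and 1, adjusted p = 1.69e-05), mitosis genes (0.77, 18 and 0, adjusted p = 0.00125) and interferon-stimulated genes (1.72, 18 and 4, adjusted p = 0.000429) were higher. With an estimated correlation the adjusted p of these lists was 0.336 to 0.673. MT-ND6, the mRNA of the mitochondrial light strand, fell in BEAS-2B cells with complete (26.2 ± 30.5 against 241 ± 48.7 CPM, -3.20 ± 0.78, adjusted p = 0.0131) and filtered smoke (10.3 ± 5.92 CPM, -4.55 ± 0.83, adjusted p = 0.00496), with counts that ignore strand at -2.08 and -2.04.

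CYP1A1, CYP1B1 and TIPARP were higher with complete than with filtered smoke in A549 cells. A stronger general response to complete smoke is argued against by the response score, which was lower with complete smoke (-0.149 ± 0.0362 SE over 3 numbers). A smooth bias by GC content or gene length, shared by all genes, is argued against for CYP1B1 alone. Its difference, which is also the median of the 3 genes, was 2.78 with block and offsets against 2.84 with the block only. Those medians say nothing on CYP1A1 or TIPARP. AhR ligands carried on particles and removed by the filter may be the source, since the median of the 3 genes was also above 0 in BEAS-2B cells (0.390 ± 0.166 SE over 3 numbers, with medians of 0.706, 0.141 and 0.325, and CYP1A1 at -0.05 in number 2). Complete smoke left CYP1A1 below clean air in that line (4.31 against 11.5 CPM), which such ligands alone do not account for, so this stays an open hypothesis found and tested on the same data.

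Exposed libraries numbered 3 had the weakest response score in all 4 exposed groups (0.600 and 0.685 in A549 cells, 0.891 and 1.14 in BEAS-2B cells). Mixing with control RNA could explain this, but it would dilute every gene alike. In A549 cells immediate early genes in number 3 reached medians of 1.16 (complete) and 1.22 (filtered smoke) of the rise in numbers 1 and 2. Their lower quartiles were 0.918 and 0.902, where other rising genes reached medians of 0.295 and 0.269. In BEAS-2B cells the medians of immediate early genes were 0.745 and 0.891. There, with complete smoke, their lower quartile of 0.633 was barely above the upper quartile of other genes (0.624). Low depth is argued against because abundant genes also fell short in 4 of 4 libraries (medians of 0.561, 0.378, 0.469 and 0.617). Reads outside genes took the largest share in number 3 of each exposed group (6.41%, 5.09%, 12.6% and 2.90%, against at most 3.73%, 2.86%, 1.40% and 1.26% in numbers 1 and 2), mitochondrial counts did in A549 cells (11.5% and 12.3%, and 9.78% in control 3) and multimapping reads in BEAS-2B cells (31.7% and 19.2%). Neither a difference in RNA or library quality nor one in dose or timing between exposure runs was tested.

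Short genes rose and long genes fell, and over 5 equal groups of abundant protein-coding genes ordered by gene span, from the shortest to the longest, the median log2 fold change went from 0.58 to -0.56 and from 0.71 to -0.63 in A549 cells with complete and filtered smoke, and from 0.96 to -0.59 and 1.02 to -0.72 in BEAS-2B cells. Bias by mature transcript length alone is argued against, since the weakest partial correlation with gene span at matched transcript length was -0.165. Over all libraries transcript length at matched span was related to the change at least as strongly (-0.358, -0.388, -0.366 and -0.361, against -0.337, -0.298, -0.226 and -0.272 for span), though not in A549 complete smoke number 3 (-0.159 against -0.391), and GC content correlated at 0.350 to 0.467, so neither is excluded as a part of the trend. The idea that a loss of new transcription should spare intronless genes was written ahead of its test, and the result went the other way. Intronless genes lay below matched genes with introns in BEAS-2B cells (-0.421 ± 0.0601 and -0.350 ± 0.0758 SE with complete and filtered smoke). They did so in A549 cells with filtered smoke (-0.168 ± 0.0593), though not beyond the spread with complete smoke (-0.0744 ± 0.0759). Genes were matched on exonic length and mean level and not on how fast their transcripts decay. The test therefore does not exclude a loss of new transcription. A change in RNA quality or in the rate of elongation may also remain, and neither was tested.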
